A study of Mus musculus with 6 samples.

How the data were processed

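RNA from mIMCD3 cells, a mouse cell line of the inner medullary collecting duct, was measured on 6 single-colour oligonucleotide arrays. Per the labels, the cells were treated with vehicle or aldosterone for 1 h, the experiment was carried out 3 times, and each replication gave 1 vehicle and 1 aldosterone array. The hormone dose, the arrays' scanning and summarisation software and the scaling target are not given in the sources used here. Because the labels describe repeats of the experiment without saying more about the cultures, the p-values measure the spread between these samples.

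The deposited values were intensities on a linear scale, 1 per probe set and array. On 5 arrays the 2% trimmed means of the deposited intensities lay between 2488 and 2493, so these arrays shared a scale as deposited. The aldosterone array of replication 3 had a trimmed mean of 86.5, lower by a factor of 28.8. The rule set before the data were examined was to keep the values if the trimmed means lay within 10% of each other and otherwise to scale each array to the mean of the trimmed means. Each array was therefore multiplied so that its trimmed mean became 2090, by factors of 0.838 to 0.840 on 5 arrays and 24.2 on the aldosterone array of replication 3. Its values were stored to 1 decimal, so low intensities are coarser on this array than on the others. Intensities were converted to log2(value + 53.0), the pseudocount being the 10th percentile of all scaled values. Fold changes refer to that scale and understate the change of dim probe sets. Probe sets with a mean log2 value of at least 8.87, the 40th percentile, were tested, which kept 7453 of 12422 and left out 4969.

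Gene symbols came from the annotation of the array's probe sets and were compared through Entrez gene identifiers with RefSeq genes of assembly GRCm38.p6, which changed 0 symbols. Of all probe sets, 10833 had 1 symbol, 396 had several and 1193 had none, and a gene was named only where a probe set had exactly 1. Where a gene was needed once, the probe set with the highest mean was taken, which gave 5640 tested genes. Coordinates are not used here.

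Groups were compared with limma 3.58.1 in R 4.3.3 by lmFit and eBayes with an intensity trend, two-sided, on group alone, with Benjamini-Hochberg adjustment over the 7453 probe sets and a threshold of 0.05. The replication number entered as a block in an alternative fit. The numbers paired the arrays: the labels describe each replication as 1 experiment, and the deviations of a replication's 2 arrays from their group means correlated at 0.377, 0.387 and 0.471 across probe sets. The pairings of different numbers gave -0.279 to -0.0853. Deviations from a group mean cancel within the group, so negative values there follow from the positive ones and are not separate evidence. With the replicate block, 250 probe sets instead of 72 had an unadjusted p under 0.05. The median standard error was 0.209 on group alone and 0.153 with the block. Standard errors given with log2 differences are from the fit on group alone, which ignores the pairing, unless stated otherwise.

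Gene lists were written before the data were examined. They numbered 22 and covered 4 genes taken to be those this study reported, corticosteroid targets, corticosteroid receptors and their partners, sodium transport, vasoactive signalling, immediate early genes, the circadian clock, collecting duct and osmolyte genes, matrix and TGF-beta genes, heat shock and endoplasmic reticulum stress, NF-kB and inflammation, the interferon response, the cell cycle, sterol synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, and markers of proximal tubule, intercalated cells, fibroblasts, endothelium and leukocytes. Lists with at least 3 tested genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists tested. Camera compares a list with the other tested genes, and fry tests a list against no change. Their genes were also counted after adjustment over the list alone. The list of 4 genes was written from general knowledge of the study, whose publication was not used here, and they are understood to have been chosen on these samples.

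Genes were named by a rule set before the data were examined. It took the 12 higher and 12 lower genes with the largest change among those past the threshold, filled up with the smallest p-values among genes that went one way in all 3 replications. It added every measured member of the lists of reported genes and of receptors, and 2 or 3 members of each other list by smallest p. It named 67 genes, and genes named outside it, among them those named for a difference between replications other than Ccn2 and Dusp1, were named after their values were seen. A count of probe sets that moved at least 1.5-fold in one direction in every replication was set beside the counts with vehicle and aldosterone exchanged within 1 replication. Differences between replications were tested afterwards with limma's F test over the replication terms of the blocked fit, and the spread of each list between replications was compared with 10000 random lists of the same size and brightness. The comparison of spread was planned for immediate early genes before its result was seen, and the F test and the spread of the other lists were added after the data were seen.

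The fit was tested on simulated arrays of 7453 probe sets with known changes, 10 times. Over the 10 simulations, 676 probe sets changed 1.5-fold, 695 changed 2-fold and 629 changed 3-fold. For the comparison of aldosterone with vehicle, the fit on group alone recovered 8.73%, 49.1% and 83.8% of these with 0 false calls per simulation. The blocked fit recovered 57.2%, 85.5% and 99.2% (387, 594 and 624) with 13.3 false calls per simulation. Its share of false calls was above the threshold set for the adjusted p. With so many changes the adjustment is milder, so these percentages do not describe data in which few probe sets respond. In limma's fit of the data on group alone, Sgk1 at 3.10-fold had an adjusted p of 0.242. The list test found a simulated 2-fold shift of 4 genes in 20 of 20 simulations. These genes were drawn independently and camera ran at its preset correlation, so the result does not cover lists whose genes move together. The comparison of 3' with 5' control probe sets planned as a check of RNA quality was not run, since such probe sets are not analysed here, and no detection calls were used. The number of arrays limits the precision of every value. The alternatives tried were the replicate block, quantile normalization, median centring, other pseudocounts and filters, no intensity trend, array weights, a plain two-sample test, 1 probe set per gene, other list tests, and leaving out each array and each replication.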

Results

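The transcripts of mIMCD3 cells were measured after 1 h with aldosterone, the adrenal steroid that drives sodium reabsorption in the distal nephron, or with vehicle, to find genes that respond early to the hormone in collecting duct cells. Each of 3 replications of the experiment gave 1 array per treatment, so both groups held 3 arrays. The median deposited intensity was 907 to 1003 on 5 arrays and 30.9 on the aldosterone array of replication 3, which was on another scale and was rescaled. After scaling, the medians of the arrays lay between 747 and 843. The median log2 value of the tested probe sets was 11.14 ± 0.031 with vehicle and 11.15 ± 0.011 with aldosterone (SD, n = 3 each; exact permutation test, two-sided, p = 0.7, where 3 against 3 arrays cannot go below 0.1). Across probe sets, log2 values of 2 arrays correlated at Pearson's r of 0.936 to 0.976, and every array correlated best with the other array of its own replication.

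The transcripts with the largest shifts after aldosterone included Sgk1, the serum- and glucocorticoid-regulated kinase that promotes sodium channel activity at the cell surface, and Per1, a component of the circadian clock. The intensity of Sgk1 was 834 ± 211 with vehicle and 2664 ± 367 with aldosterone (SD, n = 3 each), a log2 difference of 1.63 with a standard error of 0.223, or 3.10-fold. It was 2.78-fold, 2.76-fold and 3.88-fold higher in the 3 replications. Per1 went from 1090 ± 97.6 to 2692 ± 396, 2.39-fold, and was higher in 3 of 3 replications. Both probe sets of Edn1, which encodes the vasoactive peptide endothelin-1, were higher in 3 of 3 replications, at 2.38-fold for the dimmer one (2242 ± 542 against 918 ± 251) and 2.03-fold for the brighter one (2639 ± 899 against 1258 ± 357). Ccn2, the connective tissue growth factor, had 9258 ± 9473 with vehicle and 15022 ± 11359 with aldosterone. Its log2 differences of 0.44, 1.27 and 1.01 within the replications all had one direction. Its level, however, differed so much between replications that the standard error of the mean difference of 0.91 was 0.761. With the replicate block that standard error was 0.143.

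**Figure D1:**
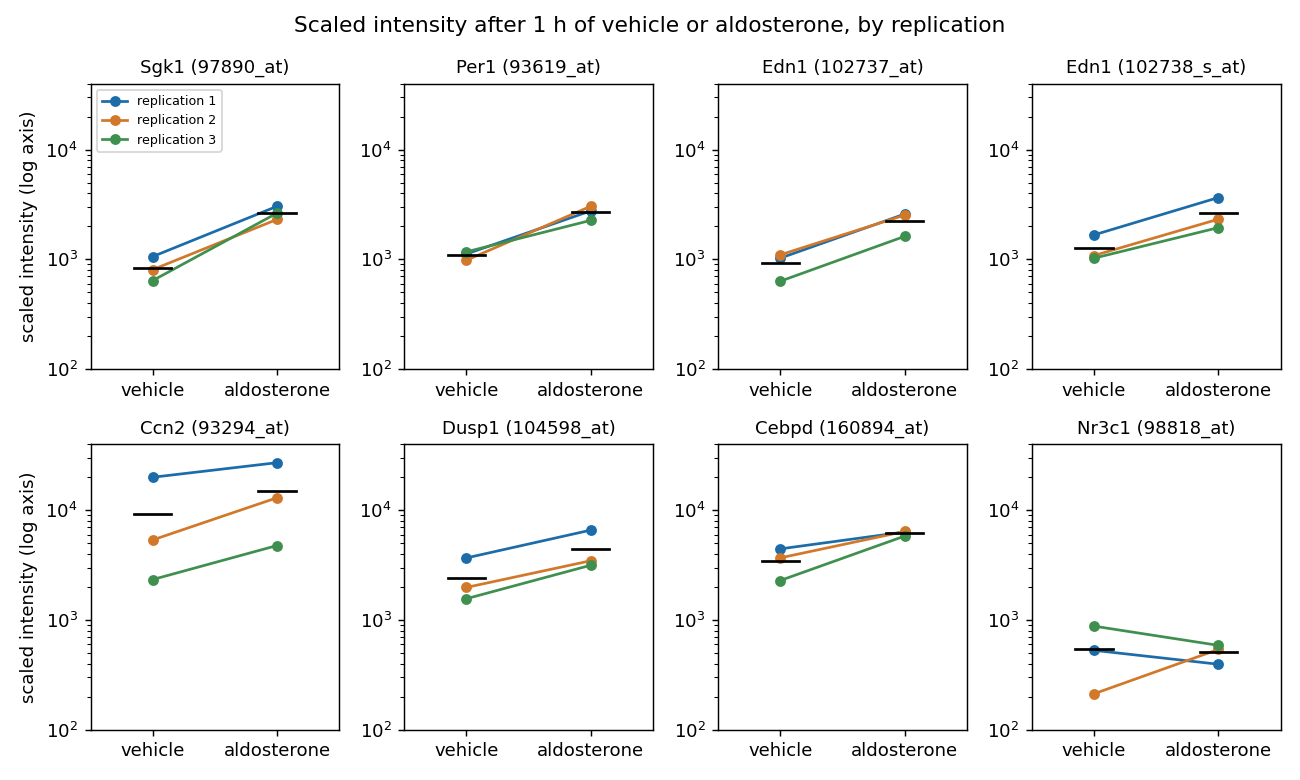
Scaled intensity on a log axis for 8 probe sets after 1 h of vehicle or aldosterone. Each point is 1 array, lines join the 2 arrays of a replication, and black bars are group means (n = 3). All 3 lines slope upward for Sgk1, Per1, both Edn1 probe sets, Ccn2, Dusp1 and Cebpd, the Ccn2 lines start at very different levels, and for Nr3c1, the glucocorticoid receptor, 1 line slopes upward and 2 downward.

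None of these differences passed the threshold over all probe sets. In limma's fit on group alone, 0 of 7453 probe sets had an adjusted p under 0.05, and the plain two-sample test also called 0. An unadjusted p under 0.05 was reached by 72, 46 higher and 26 lower. Chance would give 373 if the arrays were independent, but the 2 arrays of a replication were alike, which this fit ignores. With vehicle and aldosterone exchanged within 1 replication the same fit gave 124, 82 and 102, so 373 is not the count that chance gives here. The balance of the 72 turned to 92 higher and 170 lower of 262 when dim probe sets were included, and to 32 higher and 41 lower of 73 without the aldosterone array of replication 1. Without the vehicle array of replication 2, 1 probe set without a gene name was called. The smallest adjusted p was 0.242, for Sgk1 and for Per1. With the replicate block the count stayed at 0, with 250 probe sets at an unadjusted p under 0.05. The adjusted p in that fit was 0.0509 for Sgk1, 0.0722 for Per1, 0.0722 and 0.0922 for the probe sets of Edn1, and 0.124 for Ccn2. Other genes reached similar values, with 0.0722 for Dusp1 and 0.107 for Smyd2. Adjusted over the list alone, 3 of the 4 genes taken here to be those the study reported, Sgk1, Per1 and Edn1, passed, and with the replicate block all 4 did. The list was written from general knowledge of the study, without its publication at hand, and as these genes are understood to have been chosen on these samples, the count is not independent evidence. With camera, the list of 4 lay above the other tested genes (median log2 difference 1.14, all 4 members higher in 3 of 3 replications, adjusted p = 8.57e-16). That call was lost with an estimated correlation, where adjusted p = 0.119. Fry, which tests a list against no change and not against the other genes, gave adjusted p = 0.136, and 0.0479 with the replicate block.

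Genes listed as targets of corticosteroids were more often higher than lower, by small amounts, and whether they differed from other genes as a group depended on the test. This list shared no gene with the list of 4, so Sgk1, Per1, Edn1 and Ccn2 do not enter its values. Camera at its preset correlation placed the list above the other genes (adjusted p = 3.23e-05), but not at an estimated correlation (adjusted p = 0.231), and fry, as a test against no change, gave adjusted p = 0.834. Of the 40 genes on that list, 27 were tested, and 18 were higher and 9 lower by sign, with a median log2 difference of 0.14. In all 3 replications 10 of the 27 (37.0%) were higher and 0 were lower, against 582 (10.4%) higher and 660 (11.8%) lower of the 5613 other tested genes (Fisher's exact test, two-sided, p = 2.42e-04 for the higher share and p = 0.0662 for the lower share; this comparison was added after the data were seen, and genes are not independent replicates). Cebpd, a transcription factor of the C/EBP family, had 3480 ± 1097 with vehicle and 6201 ± 325 with aldosterone, a log2 difference of 0.87 with a standard error of 0.226. Dusp1, a phosphatase that inactivates MAP kinases, had 2412 ± 1123 and 4415 ± 1907, a log2 difference of 0.87 with a standard error of 0.348. With the replicate block the standard errors were 0.151 for Cebpd and 0.118 for Dusp1. The feedback inhibitor of EGF receptor signalling Errfi1, named after its values were seen, had log2 differences of 0.52 and 0.44 in its 2 probe sets, and Fkbp5, also named afterwards, was at 3457 with vehicle and 3459 with aldosterone.

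By limma, 0 of the 27 corticosteroid targets passed over all probe sets. Adjusted over the list alone, 0 passed (1 without the vehicle array of replication 1), and 3, Cebpd, Dusp1 and Errfi1, did with the replicate block. Without the vehicle array of replication 3 the camera call at the preset correlation was lost, at a median of 0.06 and an adjusted p of 0.128.

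**Figure D2:**
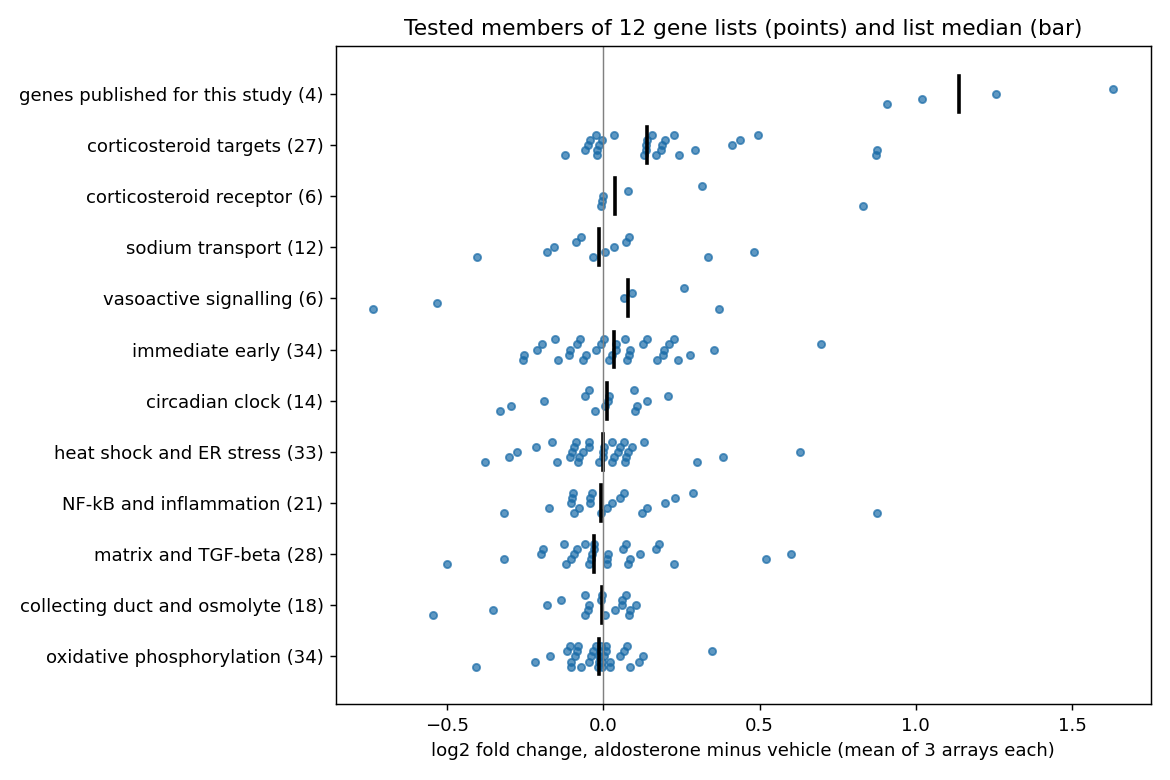
Log2 fold change, aldosterone minus vehicle (n = 3 arrays each), of the tested members of 12 gene lists. Points are genes, black bars are list medians and the number of tested genes stands in brackets; the 4 genes taken to be those published for this study lie between 0.91 and 1.63, while the other lists are centred within 0.14 of zero.

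The other 19 lists tested were not called, with camera's adjusted p between 0.720 and 0.995. The list of receptors and their partners held 13 genes, of which 8 were on the array and 6 were tested (camera's adjusted p = 0.720). The gene of the mineralocorticoid receptor was not among the 8, so no value is given for it. The glucocorticoid receptor Nr3c1 had 540 ± 334 with vehicle and 507 ± 100 with aldosterone. Its log2 difference was 0.08 with a standard error of 0.450, so its direction was not resolved. The log2 difference was -0.004 for the chaperone Hsp90aa1, -0.009 for the co-chaperone Stip1, 0.32 for the coactivator Ncoa1 and 0.83 for the coactivator Ncoa2, which was higher in 2 of 3 replications. The immunophilin Fkbp4 had -0.002 and 0.15 in its 2 probe sets. Hsd11b2, the enzyme that protects the mineralocorticoid receptor from glucocorticoids, was too dim to be tested; its 2 probe sets read 204 ± 70.6 and 197 ± 71.6 with vehicle and 133 ± 20.3 and 40.6 ± 10.2 with aldosterone, lower in 3 of 3 replications. Hsd11b1 was also too dim, at 192 ± 56.0 and 252 ± 196.

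Sodium transport genes, a classical target of aldosterone in the kidney, showed 6 of 12 tested members higher and 6 lower by sign (adjusted p = 0.995). The list held 35 genes, of which 21 were on the array, so most of it was not tested. The bicarbonate cotransporter Slc4a4 had a log2 difference of 0.48 with a standard error of 0.372, and the chloride channel Clcn3 had 0.25 in its probe set of smallest p but 0.03 in its brightest, which the list test used. Immediate early genes split into 20 higher and 14 lower (median 0.03, adjusted p = 0.720), with 0.70 for the phosphatase Dusp6 and 0.28 for Fosb. Their list was called on leaving out the vehicle array of replication 1 (median 0.29), the aldosterone array of replication 3 (0.28) or, in the other direction, the aldosterone array of replication 1 (-0.16). In these fits the groups are no longer balanced over replications, between which these genes differed. Circadian clock genes other than Per1 split into 8 higher and 6 lower (adjusted p = 0.995), counted on each gene's brightest probe set. The probe sets of smallest p gave 0.61 for the kinase Csnk1d and 0.43 for Nfil3, but the brightest ones gave -0.05 for Csnk1d and 0.14 for Nfil3. Vasoactive signalling genes, of which 6 of the 38 listed were tested, gave an adjusted p of 0.839, and the bradykinin receptor Bdkrb1 had -0.53, lower in 3 of 3 replications.

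For the remaining lists the adjusted p was 0.720 for the interferon response, hypoxia and glycolysis, and intercalated cell markers, 0.788 for collecting duct and osmolyte genes, and 0.857 for oxidative phosphorylation and leukocyte markers. It was 0.995 for matrix and TGF-beta genes, heat shock and endoplasmic reticulum stress, NF-kB and inflammation, the cell cycle, sterol synthesis, ribosomal proteins, proximal tubule markers and fibroblast markers. Among their members, the endoplasmic reticulum stress gene Herpud1 had a log2 difference of 0.38 with a standard error of 0.146, the matrix protein gene Sparc had -0.50 with 0.197, and Isg15, an interferon-induced ubiquitin-like protein, had 0.39 with 0.208. Among markers of other cell types, log2 differences were 0.53 for Kit and 0.08 for Car12 (intercalated cells), -0.46 for Gatm and 0.16 for Cyp4b1 (proximal tubule), -0.38 for Pdgfra and 0.30 for S100a4 (fibroblasts), and -0.18 for Cd14 and -0.41 for Cd68 (leukocytes). Of the endothelial markers only Eng was bright enough to be tested, at -0.73 and lower in 2 of 3 replications, so that list had no test. The median, the mean and camera's direction differed in sign for 8 lists, 0 of them called.

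Beyond the lists, the genes with the smallest p-values that were higher in every replication included Smyd2, a lysine methyltransferase, for which a probe set read 400 ± 81.2 with vehicle and 1255 ± 183 with aldosterone, 2.90-fold (adjusted p = 0.411, and 0.107 with the replicate block). Another Smyd2 probe set disagreed, with a log2 difference of 0.13 and a standard error of 0.389. The phosphatase inhibitor Ppp1r2 (0.78), the glycosyltransferase Gcnt2 (0.87), Spsb1 (0.73), Dcaf12 (0.66), the ciliary transport gene Ift88 (0.65), the zinc finger gene Zfp35 (0.61) and the kinase Pim3 (0.59) were higher by these log2 differences. Those lower in every replication were Aplf (-0.91), Mis18a (-0.84), the ADP-ribosyltransferase Tiparp (-0.79), Tm2d1 (-0.79), Cblif (-0.78), Golga7 (-0.76), Frat2 (-0.74), Taf1d (-0.60), the coatomer subunit Arcn1 (-0.57), the glutaryl-CoA dehydrogenase Gcdh (-0.55) and Rabggtb (-0.46). Brighter probe sets of several of these genes did not share the difference, with 0.08 for Ift88, 0.07 for Gcdh, -0.06 for Frat2 and -0.01 for Taf1d, and dimmer probe sets gave smaller differences, 0.22 for Ppp1r2, 0.35 for Spsb1 and -0.33 for Arcn1. The adjusted p of each of these genes other than Smyd2 was 0.9995, and none passed with the replicate block.

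A shift of at least 1.5-fold in one direction in all 3 replications was seen for 12 probe sets, 9 higher and 3 lower. The higher ones were Sgk1, Smyd2, Per1, both probe sets of Edn1, Dusp1, and, named after their values were seen, Trabd, Tigd5 and a probe set without a gene name; the lower ones were Frat2, Tm2d1 and Trh, the last named after its value was seen. With vehicle and aldosterone exchanged in 1 replication, the counts were 10, 11 and 8, so the real count was barely above them, and it fell among or below them in other settings: 42 against 71, 52 and 57 at 1.3-fold, 9 against 9, 10 and 11 after quantile normalization, and 118, of which 34 were higher and 84 lower, against 135, 105 and 97 with dim probe sets included. It was above them at 2-fold, with 3 against 0, 0 and 2, and above the 60th percentile of brightness, with 5 against 0, 0 and 0.

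The replications themselves differed more than the treatments. Limma's F test found 583 of 7453 probe sets (7.82%) that differed between replications at an adjusted p under 0.05, of which 227 were highest in replication 1, 146 in replication 2 and 210 in replication 3. Immediate early genes, which growth factors and stress induce within minutes, stood out. Of the 34 tested, 19 (55.9%) differed, and all 19 were highest in replication 1, against 417 of 5606 other tested genes that differed (Fisher's exact test, two-sided, p = 3.23e-13; genes are not independent replicates). Over all 34, 28 were highest in replication 1 among the vehicle arrays and 29 among the aldosterone arrays. Among genes named after their values were seen, the highest and lowest replication lay 4.76-fold apart for Plk2 (adjusted p = 1.21e-04), 4.31-fold for Myc (0.00284), 3.77-fold for Ccn1 (8.67e-04) and 3.76-fold for Egr1 (0.00106), and for Ccn2, which is not on that list and was named by rule, 6.89-fold (3.81e-04). Sgk1, Per1 and Edn1 did not pass this test, with adjusted p of 0.316 for Sgk1, 0.914 for Per1, and 0.0859 and 0.0550 for Edn1. Without the intensity trend in the fit the test called 2 probe sets and 0 immediate early genes, and without the vehicle or the aldosterone array of replication 1 it called 44 and 100 probe sets, with 3 and 11 immediate early genes. Without the vehicle or the aldosterone array of replication 2 it called 943 and 1292 probe sets.

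**Figure D3:**
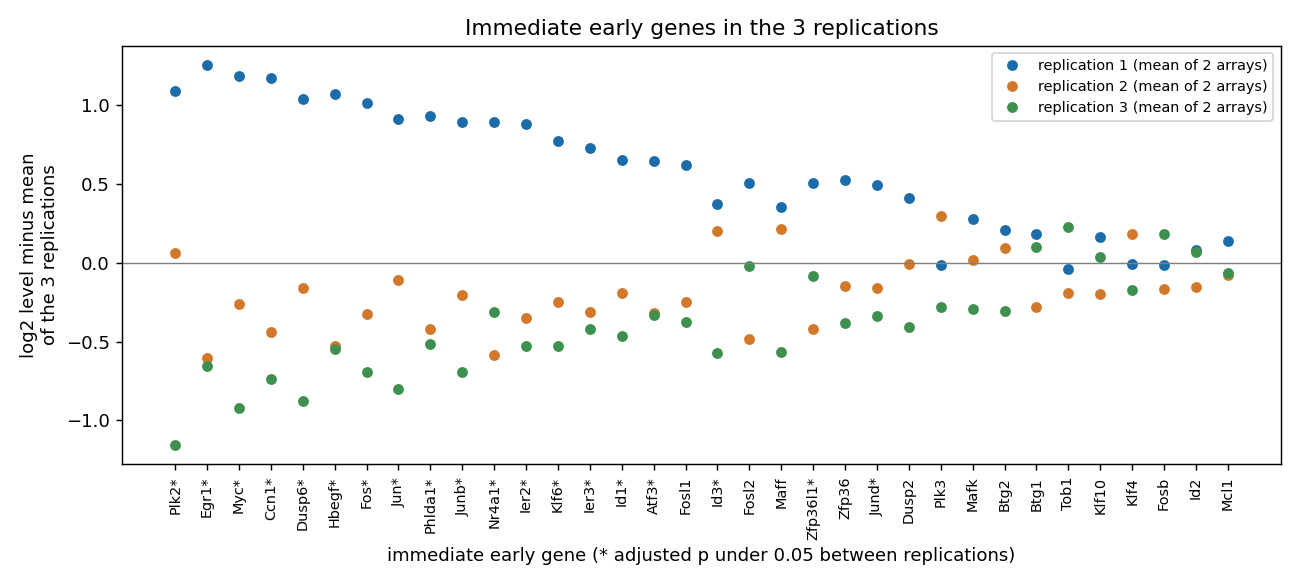
Log2 level of the 34 tested immediate early genes in each replication, minus the gene's mean over the 3 replications. Each point is the mean of the 2 arrays of a replication and an asterisk marks the 19 genes with an adjusted p under 0.05; replication 1 is highest for 30 of the 34 genes.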

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

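Sgk1, Per1, Edn1 and Ccn2 were higher after aldosterone under every alternative run, with log2 differences of 1.47 to 1.81 for Sgk1, 1.09 to 1.43 for Per1, 1.01 to 1.46 and 0.76 to 1.23 for the probe sets of Edn1, and 0.20 to 1.73 for Ccn2. The replicate block joined with no intensity trend, another filter, another list test or replications 1 and 2 alone, and the comparison of replications, were chosen after seeing the data; all others before. The count of probe sets called, 0, stayed at 0 in all but 3 alternatives. It was 1, without a gene name, without vehicle replicate 2 (leaving out arrays or replications gave 0 to 1). It was 5 with the replicate block and the filter at the 60th percentile (Sgk1, Per1, Edn1, Dusp1 and a probe set without a gene name), where fewer probe sets were tested. It was 9 with the replicate block in replications 1 and 2 alone, which held Sgk1, Per1, both probe sets of Edn1, Ccn2, Mprip, Copb2 and probe sets without a gene name. In the last 2 the cause was not tested. The blocked fit of all 3 replications gave 13.3 false calls per simulation, and replications 1 and 2 alone leave few residual degrees of freedom, so these calls may include false ones. Of probe sets at an unadjusted p under 0.05, 46 were higher and 26 lower, which turned to 92 and 170 without a filter, 32 and 41 without aldosterone replicate 1, 41 and 48 without replicate 1, and 132 and 147 with the replicate block and no intensity trend, and was 63 and 63 in the plain two-sample test. The lists called, 2, became 0 with an estimated correlation, 0 with fry, which tests against no change and not against other genes, and 0 with the replicate block and an estimated correlation, where the medians stayed at 1.14 and 0.138 but both calls were lost, 1 with the replicate block and fry, where corticosteroid targets (0.138) lost theirs, and 1 to 3 when arrays or replications were left out. Corticosteroid targets then had medians of 0.058 to 0.250, the lowest without vehicle replicate 3, and over all alternatives adjusted p of 2.73e-07 to 0.834. Immediate early genes had -0.156 to 0.288 and were called without vehicle replicate 1, higher, without aldosterone replicate 3, higher, and without aldosterone replicate 1, lower, where the fit is no longer balanced over replications. Genes called over the list alone, 3, were 7 with the replicate block, 7 with it and quantile normalization or the filter at the 60th percentile, 6 with it and no intensity trend, 6 with it in replications 1 and 2 alone, and 3 to 5 on leaving out arrays or replications, the 5 without vehicle replicate 1. Beyond the values given here and in the report, the replicate block changed no other call. Probe sets that moved one way in all 3 replications, 12, were 42 at 1.3-fold, 3 at 2-fold, 9 after quantile normalization, 118 without a filter, with 84 of them lower, and 5 above the 60th percentile; at 1.3-fold, after quantile normalization and without a filter at least 1 exchanged labelling gave more than the real one. The 583 probe sets and 19 immediate early genes that differed between replications were 2 and 0 without an intensity trend, where the cause was not tested, and 44 to 1292 and 3 to 25 when an array was left out; 44 and 3 without vehicle replicate 1, 100 and 11 without aldosterone replicate 1, 943 and 1292 probe sets without the vehicle or aldosterone array of replication 2. Signs turned for 9 named genes that passed no test: when arrays or replications were left out, Car12 had -0.19 to 0.36, Cyp4b1 -0.16 to 0.38, Eng -1.50 to 0.15, Fkbp4 -0.13 to 0.13, Hsp90aa1 -0.12 to 0.19, Ncoa1 -0.041 to 0.51, Nr3c1 -0.46 to 0.49, S100a4 -0.15 to 0.53 and Stip1 -0.059 to 0.031, and with array weights Fkbp4 had 0.021 and Nr3c1 -0.087. With the replicate block in replications 1 and 2 alone, Eng had 0.15 and Stip1 0.027. For the 19 lists not called, 4 of 451 alternatives gave a call, the 3 above for immediate early genes and 1 for oxidative phosphorylation with the replicate block in replications 1 and 2 alone, and in the 447 others a median near 0 changed sign 89 times, which is not counted as a turn because no direction was called. Leaving out 1 array leaves the fit of replications with few residual degrees of freedom, and dim probe sets, such as those of Hsd11b2, are limited by signal over background.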

Other observations

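The splits of the arrays by adjusted p, the exchanged labels and the tests of immediate early genes over group means and of their spread between replications were planned before their results were seen. The differences between replications of other genes, the splits by unadjusted p, the comparison within replications 1 and 2, the brightness-matched lists for the list of 4 genes, the comparison of these with immediate early genes within replications and the brightness comparison for Ccn2 were chosen only after the results were seen. All genes named below for a difference between replications, other than Ccn2 and Dusp1, were named after their values were seen.

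Sterol and lipid synthesis genes also varied between replications, in another order than the immediate early genes. The median between-replication SD of the 20 tested members was 0.275 log2 units, against 0.175 for random lists of the same size and brightness. The p from the share of 10000 random lists that reached that SD, adjusted over 21 lists, was 0.0266. It treats the genes of a list as independent and is too small where they move together. Of the 20, 14 were highest in replication 2. Of these, 6 passed limma's F test, all highest in replication 2: the farnesyl diphosphate synthase gene Fdps (1.55-fold between the highest and lowest replication), the lipogenic transcription factor gene Srebf1 (1.65-fold), Acly (1.48-fold), the lanosterol synthase gene Lss (2.06-fold), the squalene epoxidase gene Sqle (1.45-fold) and the fatty acid synthase gene Fasn (1.40-fold). Hmgcs1, in contrast, was lowest in replication 2 (adjusted p = 0.0656). The list of corticosteroid targets varied too (0.262 against 0.178, adjusted p from the random lists 0.0266, with the same limit), with 7 of its 8 called members highest in replication 1, among them Lcn2 (3.07-fold), Gadd45b (2.63-fold), the NF-kB inhibitor gene Nfkbia (2.42-fold) and Dusp1 (2.19-fold). Other probe sets of these genes differed less, 1.32-fold for Lcn2, 1.77-fold for Gadd45b and 1.19-fold for Nfkbia.

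The chemokine genes Cxcl1 (5.64-fold and 3.62-fold in its 2 probe sets) and Cxcl2 (5.77-fold) were highest in replication 1 and lowest in replication 3, and the tight junction gene Cldn4 was 4.81-fold lower in replication 3 than in replication 1. The RNA helicase gene Ddx6 differed 9.19-fold and 5.87-fold in 2 of its probe sets, both lowest in replication 2. Xrn1, the 5'-3' exoribonuclease gene, was also lowest in replication 2, where it read 70.1 with vehicle and 79.4 with aldosterone, too dim for a fold to be given, against 1236 and 1624 in replication 1. Another Ddx6 probe set did not share this, at 1.11-fold (adjusted p = 0.603), so the probe sets of this gene disagree.

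Aldosterone against vehicle as a whole could not be set apart from chance by regrouping the arrays, because 3 against 3 arrays give 10 splits, too few for a share under 0.05. At an adjusted p under 0.05 the real split gave 0 probe sets and the highest other split 0, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real split gave 72, also reached by 10 of 10, and the highest other gave 945; the 6 splits that keep a replication's arrays together gave 444 to 945, which points to the structure by replication described above. Among the 4 labellings that part every replication, the real one gave 72 against 124, 82 and 102, and with the replicate block 250 against 417, 352 and 344, while its smallest adjusted p was 0.0509 against 0.848, 0.928 and 0.991. For the probe sets that moved 1.5-fold in one direction in every replication, 1 of 4 labellings, the real one, reached 12, the highest other giving 11, and 4 labellings are too few to decide; the real labelling was no longer first at 1.3-fold (42, highest other 71), after quantile normalization (9, highest other 11) or without a filter (118, highest other 135).

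The 4 genes taken to be those the study reported, Sgk1, Per1, Edn1 and Ccn2, were higher after aldosterone against this background. The other scale of the third aldosterone array does not account for it, since the median log2 difference of the 4 was 1.19 in replication 1 and 1.37 in replication 2, whose arrays shared 1 scale. A shift of all probe sets of similar brightness is argued against by the genes around them: of 10000 random lists of matched brightness the highest median was 0.311, against 1.14 for the 4 genes, which stood at percentile 100; that percentile is no evidence of a response, since these genes are understood to have been chosen on these arrays. Handling of the dishes that induced immediate early genes as a group as much as these 4 is argued against by the group's medians within replications. These were -0.07, 0.19 and 0.06, and their 95% interval over replications reached 0.39, against a lowest median of 0.97 for the 4 genes. That 0.97 may be too high a mark, since the 4 genes are understood to have been chosen on these arrays. The median also does not cover a stimulus that reached only some members. Of the 34 immediate early genes, 4 were higher and 0 lower in all 3 replications, among them Dusp6 with 0.30, 1.06 and 0.74. A weaker or narrower stimulus stays open: over group means the median of the list was 0.034, but the 95% interval over replications ran from -0.27 to 0.39. Leaving out 1 array moved the median from -0.156 to 0.288. That range does not bear on the question, since such a fit is no longer balanced over replications that differed in these genes. The standard error of the mean over genes, 0.033, on which the planned test rested, is too small because these genes move together. Their estimated correlation was 0.564 in the fit on group alone, which includes the differences between replications, and 0.145 with the replicate block. Another candidate explanation that stays open is an early response of these transcripts to the hormone, as a hypothesis, which arrays of further replications or of cells with a blocked receptor would test.

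Ccn2 varied 6.89-fold between replications, far more than it differed between treatments. Spread shared by all probe sets of its brightness is argued against by its between-replication SD of 1.39 log2 units, at percentile 100 of 200 genes of similar brightness, the highest of which had 0.661. Its order followed that of the immediate early genes, whose median between-replication SD of 0.525 lay at percentile 100 of random lists of matched brightness (median 0.178, highest 0.284). As a hypothesis, both may reflect a stimulus such as serum, medium change or time out of the incubator that differed between replications and reached vehicle and aldosterone dishes alike. Whether there was such a stimulus, which it was, and whether cultures or RNA handling differed was not tested. Such a stimulus would leave Ccn2 poorly measured by group means and better by differences within replications, where the log2 differences were 0.44, 1.27 and 1.01.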
